A study of Mus musculus with 8 samples.

How the data were processed

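The samples were macrophages of epididymal white adipose tissue (eWAT), the visceral fat depot beside the epididymis, taken from 4 male MitoFat mice on normal chow. MitoFat mice carry a reporter of adipocyte mitochondria. Per the labels' protocols, the stromal vascular fraction was freed with collagenase, stained, and sorted as live cells positive for the leukocyte marker CD45 and the macrophage markers F4/80 and CD64. Each mouse gave 1 population without the reporter signal (mtD2−) and 1 with it (mtD2+), which makes 8 libraries, 4 per group. Per the labels, RNA was extracted with a micro-scale column kit and amplified with the SMARTer Ultra-Low RNA kit, which starts from small amounts of RNA. The strandedness of the counting and the number of cells sorted are not given in the sources used here. The labels place all libraries on the same sequencing run and lane.

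Per the submitters' processing notes, the authors' tools were bcl2fastq, STAR 2.0.4b and featureCounts 1.45 of Subread, with the mouse genome build GRCm38. The notes give neither the role nor the order of these tools nor their options. The authors deposited 1 table per library with 3 values for each of 41388 Ensembl genes. The deposited counts are whole numbers of reads per gene, not normalised. The deposited CPM is the count scaled to the library's own total, and the deposited RPKM is that CPM divided by the gene length in kilobases. Both relations were checked on every library and held within rounding. Neither CPM nor RPKM was used in a test. Levels are printed as another CPM, scaled to each library's total over the tested genes times its TMM factor from the edgeR test described next. They are given with the SD over the 4 libraries of a group. Shares of counts in percent use the library's own total instead. Coordinates are the gene spans on GRCm38. Symbols, biotypes, GC content and 3′ UTRs came from the GENCODE M21 annotation of the same build, in which 40340 gene identifiers had a symbol and 1048 had none. The genes with no symbol took at most 0.4256% of a library's counts and were tested like the others. No table entry lacked a gene.

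Counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F test with TMM factors and the mouse as a block, then the group. All log2 fold changes are mtD2+ over mtD2−, and the SE is the fold change divided by the square root of its F value. Genes were kept by edgeR's expression filter (a minimum count of 10, a minimum total of 15 and a large-sample proportion of 0.7), which left 13933 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all adjusted p-values of single genes come from this test unless another tool is named. Pairing rests on the labels, which give the mouse of each library. The 2 libraries of a mouse deviated from their group means with correlations of 0.039, 0.07, 0.145 and 0.251 across genes for mice 1 to 4, and the highest correlation of the mtD2− library with an mtD2+ library of another mouse was 0.058, 0.025, 0.014 and −0.01. By this measure the pairing does not show in mouse 1. Gene lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, which compares the genes of a list with all others, adjusted over 39 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance, were run beside it. For each list the calls were also counted with p-values adjusted over the list alone. Shares of counts per library were compared with exact paired sign-flip permutation tests, two-sided, whose smallest p with 4 pairs is 0.125, so that they cannot reach 0.05.

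The following were fixed before the data were examined: the groups, the test and its block, the 39 gene lists, the alternative settings and the rule for named genes. By that rule the text names the 3 sort markers. It names the 10 higher and the 10 lower genes with the largest fold changes among called genes that moved 1 way in all 4 mice, had a mean of at least 5 CPM and had a symbol other than a Gm number, a Rik name or an antigen receptor segment. From each list it names up to 4 tested members with the smallest unadjusted p, and those that did not pass the test are given as values. Some members that the rule takes are not reported here. A gene named outside the rule is said to be so.

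The alternatives were a model without the block, 3 other scalings, 2 other low-count filters, 3 other tests (the Wald test of DESeq2 1.42.0, limma voom and robust edgeR), a fold threshold of 1.2, counts thinned to the smallest library, a correction for gene length and GC with the block kept, protein-coding genes alone, and leaving out each mouse in turn. No alternative was added later. The test was tried on simulated counts with the real means, library sizes and pairs. It called 14% of 50 genes changed 1.5-fold, 40.8% of 49 changed 2-fold, 62.5% of 48 changed 3-fold and 71.4% of 49 changed 4-fold, and 3 of 13135 unchanged genes. In the simulation, changes of 2-fold or less were mostly missed. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables, permutation tests and plots.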

Results

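RNA was sequenced from eWAT macrophages of 4 male MitoFat mice on normal chow. In each mouse, macrophages that held adipocyte-derived mitochondria (mtD2+) were sorted apart from macrophages that did not (mtD2−), so that the 8 libraries form 4 pairs. The tables hold 25285299, 24659210, 22379544 and 23614746 gene-assigned counts for the mtD2− libraries of mice 1 to 4, and 22350448, 27464399, 22635843 and 18462287 for the mtD2+ libraries. Between 17285 and 19073 genes had at least 1 count in a library. No library repeated another of its group: replicate pairs differed by 38.8 to 174.1 times the counting noise (chi-square per degree of freedom). The first principal component held 26.4% of the variance. It parted the populations, with the mtD2− libraries at −81.1 to −3.6 and the mtD2+ libraries at 18.7 to 60.5. The mtD2− library of mouse 4 lay farthest out on it (−81.1, against −28.3 to 60.5 for the other libraries). The design asks how macrophages that took up adipocyte mitochondria differ in gene expression from neighbours in the same fat pad that did not.

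Macrophages with adipocyte mitochondria had more RNA of 9 of 30 interferon-response genes, 7 of 22 inflammatory cytokine and chemokine genes, 7 of 24 dissociation-responsive genes, the autophagy receptor Optn and the glycolytic enzyme Hk2. Their libraries held less RNA of type I and type VI collagen chains, of 6 of 14 MHC class II genes and of the chemokine receptors Cx3cr1 and Ccr2. With an estimated correlation among genes, the list test gave an adjusted p of 0.658 for the interferon, inflammatory and MHC class II lists and 0.718 for the dissociation list. Ifit1, an interferon-induced gene, rose 4.01-fold, from 132 ± 68.6 to 506 ± 200 CPM (SD, n = 4 mice). Col1a2, a chain of type I collagen, fell 5.90-fold, from 135 ± 18.6 to 23.1 ± 4.65 CPM (n = 4). Of 13933 genes tested, 767 passed an adjusted p of 0.05, 519 higher and 248 lower in mtD2+, and 181 and 86 of these changed at least 2-fold. All 767 moved the same way in the 4 mice, as did 32.4% of all tested genes. The biological coefficient of variation was 33.7%. Without the mouse block 218 genes passed, 147 higher and 71 lower. With library totals in place of TMM factors the split was 407 higher to 349 lower (53.8% higher, against 67.7%). Leaving out mouse 1, 2, 3 or 4 left 215, 273, 166 or 555 calls. Of 100 called genes named in the text, 33 also passed without the block, among them Ifit1, Optn, Hk2, Ccl2, Cx3cr1 and Col1a2.

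The sort markers did not all have the same level in the paired populations. Ptprc, which encodes CD45 (chromosome 1, 138063407 to 138175706), stood at 459.8 ± 65.7 CPM in mtD2− and 464.3 ± 45.7 in mtD2+ (log2 fold change 0.02, SE 0.11, adjusted p = 0.938). Per mouse it was 539.2, 437.1, 479.1 and 383.9 CPM in mtD2− and 526.4, 417.1, 451.1 and 462.5 in mtD2+. Its sign turned under 3 other settings, to −0.04 with library totals alone, −0.28 with the length and GC correction and −0.06 without mouse 4, and no setting called it. Adgre1, which encodes F4/80 (chromosome 17, 57358686 to 57483529), fell from 718.8, 583.5, 639.1 and 800.2 CPM to 441.3, 511.2, 421.0 and 489.0 in mice 1 to 4 (log2 −0.55, SE 0.12, adjusted p = 0.0336). That call was lost without the block and on leaving out any of 3 mice (log2 −0.67 to −0.50). Fcgr1, which encodes CD64 (chromosome 3, 96282909 to 96293969), was at 157.6, 163.8, 159.9 and 157.2 CPM in mtD2− and 112.3, 138.0, 102.2 and 121.3 in mtD2+ (log2 −0.44, SE 0.11, adjusted p = 0.0554). Of the 3, 1 was lower over all genes tested and 2 when adjusted over the list alone (camera adjusted p = 0.0771).

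Among the genes that rose most, Ifit1 (chromosome 19, 34640871 to 34650009) had a log2 fold change of 2.00 (SE 0.16, adjusted p = 0.00128). Optn, an autophagy receptor that can bind damaged mitochondria (chromosome 2, 5020642 to 5064051), rose 1.74 (SE 0.22, adjusted p = 0.00481), from 27.9 ± 14.0 to 87.9 ± 30.2 CPM. Bhlhe41 and Ciart, both transcriptional repressors of the circadian clock, rose 1.67 each (SE 0.19 and 0.20, adjusted p = 0.00323 and 0.00377). Cd209c, a C-type lectin gene of a multigene family whose reads are uncertain for that reason, rose 1.68 (SE 0.18), and the long non-coding RNA Gdap10 rose 1.81 (SE 0.18). The secreted factor Prok2 rose 2.01 (SE 0.39, adjusted p = 0.0232), from 6.31 ± 3.08 to 23.4 ± 4.39 CPM. The others were Serpinf2 at 1.84 (SE 0.21), the cation channel gene Trpm1 at 1.70 (SE 0.34) and Ifitm10 at 1.67 (SE 0.22). Prok2 and Trpm1 lost the call on leaving out any of 3 mice, with fold changes of 1.56 to 2.42 and 1.36 to 1.93, and the other 8 kept it whichever mouse was left out. Ciart and Ifitm10 lost it without the block.

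Of the 10 genes that fell furthest by the rule for named genes, 4 encode collagen chains. Col1a2 (chromosome 6, 4504814 to 4541543) had a log2 fold change of −2.56 (SE 0.14, adjusted p = 0.000327), and Col1a1 (chromosome 11, 94936224 to 94953042), the other chain of type I collagen, −2.51 (SE 0.19, adjusted p = 0.0012). Col6a5, a chain of type VI collagen, fell from a mean of 33.2 CPM to 1.47 ± 1.10 CPM (log2 −4.42, SE 0.71, adjusted p = 0.0111). Col6a3, another type VI chain, fell by 2.74 on the log2 scale (SE 0.39). The complement component C7 fell from 111.6 ± 63.5 to 16.0 ± 3.80 CPM (log2 −2.64, SE 0.35, adjusted p = 0.00554). Bmper, Islr, Aebp1, Mfap4 and Cyp1b1 changed by −2.85, −2.79, −2.76, −2.71 and −2.58 (SE 0.41 to 0.60). Without the block Col6a3, Bmper, Islr, Aebp1 and Mfap4 lost their calls. Col1a1, Col1a2, Col6a3 and C7 kept their calls whichever mouse was left out. The other 6 lost theirs without at least 1 mouse, and over the fits without each mouse their fold changes spanned −5.04 to −3.63 for Col6a5, −3.18 to −2.31 for Bmper, −3.1 to −2.23 for Islr, −3.37 to −2.13 for Aebp1, −3.25 to −2.38 for Mfap4 and −2.89 to −2.04 for Cyp1b1.

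Markers of fibroblasts and adipocyte precursors, cells outside the macrophage gate, were lower as a group in mtD2+ (median log2 −1.69 over 19 tested, camera adjusted p = 3.04e-25, but 0.451 with an estimated correlation). Of these, 10 fell and 1 rose over all genes tested, and 13 fell and 1 rose when adjusted over the list alone. Besides the type I collagens, Col6a1 fell from 49.9 ± 4.6 to 9.19 ± 2.57 CPM (log2 −2.47, SE 0.21) and Col3a1 from 166.1 ± 42.8 to 36.3 ± 4.16 CPM (log2 −2.16, SE 0.19). The gene that rose was Icam1, an adhesion molecule that macrophages also make (log2 0.94, SE 0.14, adjusted p = 0.00768), named after its value was seen, and its call was lost without either of 2 mice (0.85 to 1.09). The summed list was lower in each mouse, with log2 ratios of −0.68, −0.57, −0.98 and −1.75 for mice 1 to 4.

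Genes of MHC class II presentation were lower in mtD2+ (median −0.40 over 14 tested, camera adjusted p = 0.00166, but 0.658 with an estimated correlation). Of these, 6 fell and 1 rose, with the same counts adjusted over the list alone. H2-DMb1 fell by 0.73 (SE 0.11, adjusted p = 0.00822), H2-Eb1 by 0.61 (SE 0.10), H2-Aa by 0.59 (SE 0.09) and H2-DMa by 0.66 (SE 0.11) on the log2 scale. The gene that rose was the costimulatory ligand gene Cd86 (log2 0.60, SE 0.12, adjusted p = 0.0274), named after its value was seen. The summed list was lower in each mouse, by log2 ratios of −0.47, −0.42, −0.48 and −0.79 for mice 1 to 4, as the fibroblast list was. The call of H2-DMb1 was lost without 1 mouse, those of H2-Eb1, H2-Aa and H2-DMa without either of 2, and that of Cd86 without any 1 of the 4. Over the fits without each mouse their log2 fold changes lay from −0.81 to −0.68, −0.65 to −0.56, −0.62 to −0.55, −0.70 to −0.58 and 0.52 to 0.69.

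Among 12 pan-macrophage genes, 3 fell and 1 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.0821). Cx3cr1, the fractalkine receptor, fell from 169.1 ± 35.9 to 77.8 ± 11.6 CPM (log2 −1.11, SE 0.13, adjusted p = 0.00323). Aif1 and the Fc receptor chain Fcer1g fell by 0.64 and 0.44, and the efferocytosis receptor Mertk rose 0.51. Of 18 monocyte and recently recruited macrophage genes, 2 fell and 1 rose (3 and 1 over the list alone, median −0.51, or −0.256 without mouse 4, camera adjusted p = 0.145). Ccr2, the receptor for the monocyte chemokine Ccl2, fell by 0.74 (SE 0.11, adjusted p = 0.00813), S100a6 fell by 0.60, and the lectin Clec4e rose 1.03. Among 24 resident perivascular genes, Stab1 rose 0.54 and Pf4 fell by 0.56 (1 and 2 over the list alone, camera adjusted p = 0.927). Of 22 lipid-associated macrophage genes, the lipid droplet coat gene Plin2 rose 0.63 and Acp5 rose 0.88, while Lgals1 fell by 0.45 (2 and 1 over the list alone, camera adjusted p = 0.626). Of 20 alternative activation genes, Ccl8 rose 0.65 and Irf4 rose 0.53, while Mgl2 fell by 0.65 (5 and 2 over the list alone, camera adjusted p = 0.303). Cx3cr1 kept its call whichever mouse was left out, and each other gene called here lost it on leaving out any of at least 2 mice.

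Of 22 pro-inflammatory cytokine and chemokine genes, 7 rose and 0 fell over all genes tested, and 14 rose when adjusted over the list alone (median 0.67, camera adjusted p = 2.61e-09, but 0.658 with an estimated correlation). Ccl2, which draws monocytes, rose from 1846 ± 601 to 3907 ± 502 CPM (log2 1.13, SE 0.15, adjusted p = 0.00495). The neutrophil chemokines Cxcl1 and Cxcl2 rose 1.02 each (SE 0.15 and 0.17), and the inflammasome sensor Nlrp3 rose 1.16 (SE 0.20). Of 30 type I interferon response genes, 9 rose and 0 fell by either adjustment (median 0.08, or 0.025 to 0.129 on leaving out each mouse, mean 0.35, camera adjusted p = 1.91e-05, but 0.658 with an estimated correlation and 0.0508 without the block). After Ifit1 the genes of smallest p were Ifit2 at 1.65 (SE 0.14), Oasl1 at 1.47 (SE 0.13) and the RNA sensor Ifih1 at 1.30 (SE 0.13). The summed interferon list was higher by log2 0.65, 0.85, 0.63 and 0.56 in mice 1 to 4, and the summed cytokine list by 0.79, 1.05, 1.22 and 0.18. Cxcl1 and Nlrp3 each lost the call without either of 2 mice and Cxcl2 without any of 3, with fold changes of 0.90 to 1.19, 0.95 to 1.36 and 0.86 to 1.22.

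Of 24 immediate early and heat shock genes known to respond to tissue dissociation, 7 rose and 0 fell, 12 when adjusted over the list alone (median 0.38, or 0.608 without mouse 4, camera adjusted p = 4.63e-07, but 0.718 with an estimated correlation). Dnaja1 rose 0.94 (SE 0.12, adjusted p = 0.00486), Hsp90aa1 0.82 (SE 0.13), Ppp1r15a 0.98 (SE 0.17) and Hspa8 0.70 (SE 0.12). Their summed level was higher in mice 1, 2 and 3 (log2 0.55, 0.83 and 0.67) and not in mouse 4 (−0.03), the mouse in which the summed cytokine list also rose least. For both sums the mtD2− library of mouse 4 was the highest of its group. It stood at 29954 CPM for the dissociation list, against 14791 to 20593, and at 24993 CPM for the cytokine list, against 8777 to 16213. Whether tissue dissociation raised the cytokine genes too was not tested. Of 23 genes of mitochondrial stress and the integrated stress response, 4 rose and 0 fell, 5 when adjusted over the list alone (median 0.34, or 0.049 without mouse 4, camera adjusted p = 0.0387, but 0.658 with an estimated correlation). Those were the mitochondrial chaperonin Hspe1 (1.22, SE 0.13, adjusted p = 0.00249), Ppp1r15a, Nupr1 (0.53, SE 0.12) and Atf4, the transcription factor of the response (0.54, SE 0.13). The list passed neither without the block (0.0911) nor without mouse 1 (0.0796), 2 (0.133) or 3 (0.0621). Hspe1 and heat shock genes have near-identical pseudogene copies, so their counts are uncertain. Dnaja1 and Hspe1 kept their calls whichever mouse was left out, and Hsp90aa1 (0.71 to 0.91), Ppp1r15a (0.82 to 1.203), Hspa8 (0.56 to 0.75), Nupr1 (0.46 to 0.63) and Atf4 (0.46 to 0.67) each lost it without at least 2 in turn.

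The list medians of the respiratory chain genes of the nuclear and the mitochondrial genome had opposite signs. All 8 tested mRNAs of the mitochondrial genome had a positive log2 fold change, with 0 past the test over all genes and 7 when adjusted over the list alone (median 0.75, or 0.405 without mouse 4, camera adjusted p = 8.41e-04, but 0.718 with an estimated correlation). mt-Co1 stood at 3890 ± 1613 CPM in mtD2− and 6312 ± 1136 in mtD2+ (log2 0.82, SE 0.21, adjusted p = 0.0612). mt-Cytb, mt-Nd4 and mt-Nd1 stood at 0.89, 0.78 and 0.73 (SE 0.24 to 0.25, adjusted p = 0.079, 0.0973 and 0.113). At an unadjusted p of 0.05 edgeR passed 7 of the 8, the DESeq2 Wald test called 6 higher after adjustment and limma voom 3. The other 5 mitochondrial mRNAs had almost no counts and were not tested. The options of the counting that could set this are not given in the sources used here, so the shares and sums of mitochondrial mRNA in effect leave these 5 out. The share of counts on mitochondrial mRNAs was 1.73 ± 0.807% in mtD2− and 2.54 ± 0.509% in mtD2+, higher in 4 of 4 mice (mean log2 ratio 0.74, exact paired p = 0.125). The mtD2− library of mouse 4 had 0.524%, against 2.05 to 2.26% in the other 3, and without that mouse the mean log2 ratio was 0.35. Of 76 nuclear-encoded genes of oxidative phosphorylation, 1 fell and 0 rose over all genes tested with edgeR, and 22 fell and 2 rose when adjusted over the list alone (median −0.30, camera adjusted p = 3.29e-10, but 0.658 with an estimated correlation). After adjustment DESeq2 called 15 lower and 2 higher, and limma voom 5 lower. Ndufc2 fell by 0.58 (SE 0.13, adjusted p = 0.0423), a call lost without any 1 mouse, while Ndufa13 and Uqcrc1 stood at −0.42 and −0.60 (SE 0.11 and 0.15).

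**Figure D1:**
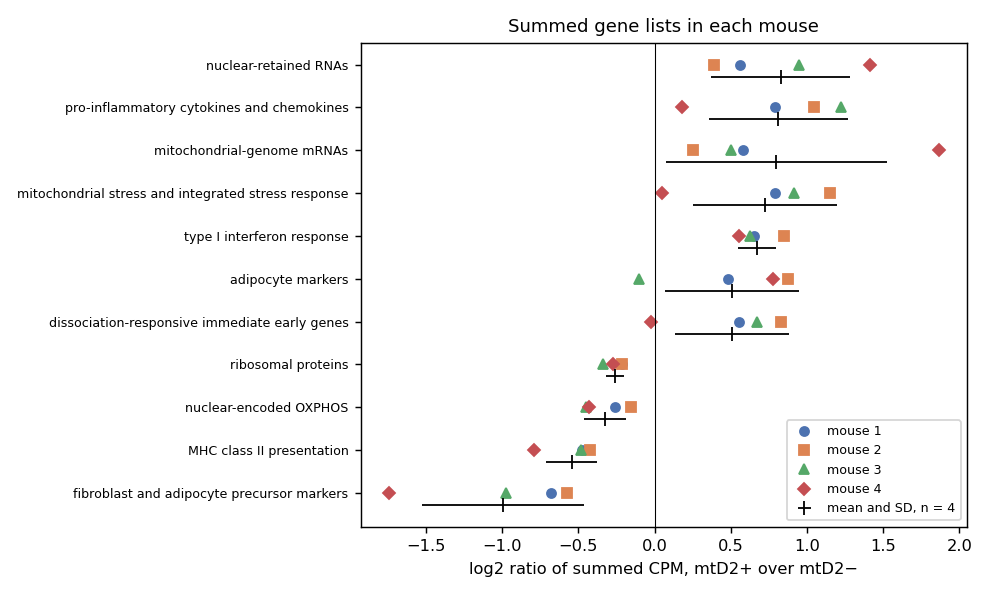
Log2 ratio of summed CPM, mtD2+ over mtD2− (horizontal axis), for the 11 gene lists past the camera test (vertical axis), with 1 symbol per mouse and the mean and SD over 4 mice below. Fibroblast genes lie at −1.75 to −0.57 and type I interferon response genes at 0.56 to 0.85, while mouse 4 stands apart for mitochondrial-genome mRNAs at 1.87.

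Of 76 ribosomal protein genes, 3 fell and 1 rose, among them Rpl7, which fell by 0.49, and Rpl10, which rose 0.77 (1 lower and 1 higher adjusted over the list alone, median −0.22, camera adjusted p = 0.00262, but 0.658 with an estimated correlation). These genes have many processed pseudogenes, so single members are uncertain, and the calls of Rpl7 and Rpl10 were each lost on leaving out any of at least 3 mice. Of 4 nuclear-retained RNAs, Neat1 rose from 894.3 ± 159.5 to 2394 ± 886 CPM (log2 1.37, SE 0.21, adjusted p = 0.00962) and Malat1 rose 0.80 (SE 0.17, adjusted p = 0.028), and 3 rose when adjusted over the list alone (camera adjusted p = 0.00291, but 0.658 with an estimated correlation). Across biotypes, 60 of 1713 tested genes that are not protein-coding rose and 1 fell, against 459 and 247 of the 12220 protein-coding genes (Fisher's exact test on the called genes, two-sided p = 6.56e-10). Rising calls were about as frequent in both sets, and the difference lay in the genes that fell. The test treats genes as independent replicates, which genes of the same libraries are not. Of the 60, 4 had no biotype in the annotation, and the rest included 15 of 424 antisense genes, 15 of 314 lincRNA genes and 5 of 27 sense-intronic genes. Reads of antisense and intronic genes cannot be told from those of their partner gene where strand was not used. Long non-coding RNA (lincRNA, antisense and sense-intronic genes) took 4.28 ± 0.701% of counts in mtD2− and 5.62 ± 0.949% in mtD2+ (4 of 4 mice, exact paired p = 0.125). The summed nuclear-retained list alone stood at 21736 ± 6673 CPM in mtD2− and 37535 ± 8906 in mtD2+. Its few genes could account for the rise in that share, and the share without them was not tested. Neat1 lost its call without 1 mouse (1.08 to 1.55) and Malat1 without either of 2 (0.59 to 0.96).

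Of the lists of lysosome, autophagy, glycolysis, fatty acid oxidation, cholesterol, LXR target and iron genes, 0 passed the camera test. Of 45 lysosome genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.344). The sialidase Neu1 rose 0.99 (SE 0.11, adjusted p = 0.00323), the proton pump subunit Atp6v1a 0.88 (SE 0.12) and the galactosidase Gla 0.92 (SE 0.14). Of 28 mitophagy and autophagy genes, Optn and its kinase Tbk1 (0.63, SE 0.13) rose and the mitophagy receptor Fundc1 fell by 0.55 (4 and 1 over the list alone, camera adjusted p = 0.125). Hk2 rose from 91.2 ± 28.9 to 246.8 ± 23.9 CPM (log2 1.49, SE 0.14, adjusted p = 0.00175) and Pfkfb3, which drives glycolytic flux, rose 1.05 (SE 0.14), the 2 called of 21 glycolysis genes by either adjustment (camera adjusted p = 0.453). Of 22 fatty acid oxidation genes, 2 rose and 1 fell, among them Acadvl, which rose 0.85, and Echs1, which fell by 0.55 (2 and 3 over the list alone, camera adjusted p = 0.187). Of 20 cholesterol synthesis genes, Insig1 rose 1.11 and Sc5d 0.92 (2 over the list alone, camera adjusted p = 0.734), and of 16 LXR target genes Mylip rose 1.16 (2 over the list alone, camera adjusted p = 0.82). Of 21 iron and heme genes, Slc11a2 rose 1.13, Tfrc 0.67, Hmox1 0.62 and Spic 0.53, and Steap4, named after its value was seen, fell by 1.61 (the same counts over the list alone, camera adjusted p = 0.453). The list medians of glycolysis, cholesterol synthesis and iron genes (−0.03, −0.10 and −0.06) had the opposite sign to their means (0.02, 0.09 and 0.03) and to the camera direction, and on leaving out each mouse they ran from −0.102 to 0.014, −0.215 to −0.001 and −0.106 to 0.011. Neu1, Atp6v1a, Hk2, Pfkfb3, Acadvl, Mylip and Optn kept their calls whichever mouse was left out, and the others named here did not. Without the block Neu1, Atp6v1a, Acadvl and Mylip lost theirs too.

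Of the remaining lists of cell function, 0 passed the camera test. Of 31 phagocytic and scavenger receptor genes, 6 fell and 2 rose (11 and 6 adjusted over the list alone, camera adjusted p = 0.196), among them Axl at −0.57, the Fc receptor Fcgr4 at −0.88 and Cd93 at −0.58. Of 30 heparan sulfate genes, the proteoglycan core gene Hspg2 fell by 2.49 (2 lower and 1 higher over the list alone, camera adjusted p = 0.248). Of 22 antioxidant genes, Hmox1 and Txnrd1 (0.64) rose (3 higher and 1 lower over the list alone, camera adjusted p = 0.377). Of 26 mitochondrial biogenesis and dynamics genes, Pprc1 rose 0.67 (1 over the list alone, camera adjusted p = 0.812). Of 30 cell cycle genes, Pcna rose 0.53 and Mcm6 fell by 0.88 (the same counts over the list alone, camera adjusted p = 0.388). Of 18 tricarboxylic acid cycle genes, 0 passed the edgeR test by either adjustment (camera adjusted p = 0.176), with 3 lower and 1 higher at an unadjusted p of 0.05 and 1 called lower by DESeq2 and by limma voom. Each call named here was lost on leaving out any of at least 3 mice.

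Markers of other cell types were also compared. Of 20 adipocyte markers, 18 were higher in mtD2+ and 0 passed by either adjustment (median 0.56, camera adjusted p = 0.00291, but 0.658 with an estimated correlation). At an unadjusted p of 0.05 edgeR passed 5, DESeq2 called 5 after adjustment and limma voom 1, all higher. Thrsp, Cfd and Car3 stood at 0.92, 0.48 and 0.57 (SE 0.14 to 0.24, adjusted p = 0.0631, 0.0838 and 0.12). These markers took 0.0736 ± 0.0095% of counts in mtD2− and 0.102 ± 0.0229% in mtD2+ (3 of 4 mice, exact paired p = 0.25). Cd79b fell by 0.92 among 6 B cell genes and Batf3 by 0.72 among 12 dendritic cell genes (1 and 2 lower adjusted over the list alone, camera adjusted p = 0.339 and 0.453), calls lost on leaving out any of at least 3 mice. None of the 9 endothelial, 9 mesothelial, 6 smooth muscle, 3 neutrophil, 4 mast cell, 9 lymphoid or 8 erythroid markers tested passed over all genes with edgeR. At an unadjusted p of 0.05 edgeR passed 2 endothelial, 2 mesothelial, 1 smooth muscle, 1 lymphoid and 6 erythroid markers. After adjustment DESeq2 called 1 endothelial, 1 smooth muscle, 1 lymphoid, 1 mast cell (all higher) and 4 erythroid (lower) markers, and limma voom 1 erythroid marker. Adjusted over the list alone, 1 lymphoid marker was higher, and 5 erythroid markers were lower and 1 higher. The camera adjusted p-values of these 7 lists ran from 0.0771 for erythroid markers to 0.945 for neutrophil markers. The dendritic cell list had a median of 0.05 (−0.363 to 0.123 on leaving out each mouse) and a mean of −0.08, the lymphoid list 0.25 (−0.014 to 0.776) and −0.02, and the neutrophil list a positive median against a negative camera direction.

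**Figure D2:**
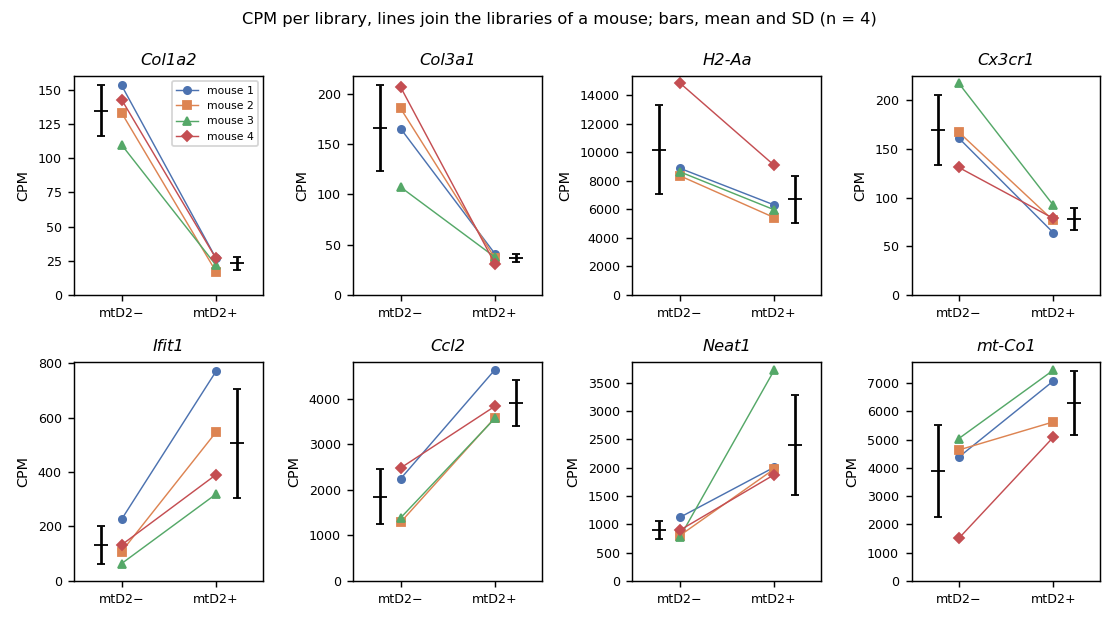
CPM of 8 genes (vertical axes, from 0) in the mtD2− and mtD2+ library of each mouse, joined by a line, with the mean and SD of each group (n = 4). Every line falls for Col1a2, Col3a1, H2-Aa and Cx3cr1 and rises for Ifit1, Ccl2, Neat1 and mt-Co1, and the mtD2− library of mouse 4 has the lowest mt-Co1 level at 1504 CPM.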

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

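The tests on mitochondrial ribosomal RNA, on the nuclear-encoded respiratory chain genes and on library totals were chosen only after their results were seen, and the readings of the tests of the splits without the block, of matrix transcription, of cytosolic RNA loss and of the clock were made more cautious after their values were seen. Of 80 groups of 4 libraries examined, 9 had 1 library far from the other 3, where chance gives about 1 in 20, or 4 groups. These groups are not independent, since they share libraries and some measures overlap, such as the share and the sum of mitochondrial mRNA. The excess of 9 over 4 is therefore not a test. The number given for each is the gap to the nearest library as a share of the group's range. The mtD2− library of mouse 4 was the distant one for the percentage of mitochondrial mRNA (0.88; 0.524% against 2.05 to 2.26%), for the summed mitochondrial mRNAs (0.863; 5694 CPM against 19117 to 21248), for the nuclear-retained RNAs (0.88; 11796 against 24423 to 26150), for the fibroblast list (0.911; 5205 against 2105 to 2382), for the MHC class II list (0.871; 103903 against 52761 to 59376) and for Bmper (0.867; 28.2 against 8.66 to 11.3). The mtD2+ library of the same mouse was distant for the MHC class II list (0.843; 59983 against 39309 to 42550) and for Prok2 (0.856; 16.9 against 24.7 to 26.0). The mtD2+ library of mouse 1 was distant for Mfap4 (0.906; 10.5 CPM against 1.64 to 2.48). Not every fibroblast gene was distant in the mtD2− library of mouse 4. Col1a1 and Col1a2 stood at 102 and 143 CPM there, against 64.6 to 125 and 110 to 154 in the other 3. A second fibroblast list, given below, summed to 2347 CPM, against 1518 to 1841. Which members raised the first sum was not examined.

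Other splits of the 8 libraries were fitted with edgeR to see how many genes they call. Since the libraries are paired by mouse, the real split was compared with the 8 that part all 4 pairs, itself included, and 8 are too few for a share under 0.05. The real split gave 218 genes without the block and 767 with it, and the highest of the others gave 0 in each case. The other 7 exchange the populations in 1 or 2 mice, so that the real difference enters their residual spread.

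The summed list of fibroblast genes was lower in mtD2+ in all 4 mice, although Icam1, 1 of its members, rose. One mouse with fibroblast RNA in its mtD2− library is argued against by the weakest of the 4 log2 ratios of the summed list, −0.574, and by medians of −1.73 to −1.42 with each mouse left out. A larger amount of fibroblast or precursor RNA in the mtD2− libraries stays open and is consistent with a second list of 25 fibroblast genes, 16 of them called lower, with a median of −1.544, although the gate on CD45, F4/80 and CD64 would remove intact fibroblasts. A lower transcription of matrix genes in the macrophages alone stays open too. A list of 19 fibroblast genes taken as non-matrix had a median of −1.224 (bootstrap −2.049 to −0.616), beyond the bound written in advance, but that bound made no allowance for low counts. Of the 19, 16 had a mean under 10 CPM, and leaving out each mouse moved the median from −1.699 to −0.709. The other 3, Gfpt2, Cxcl12 and Anxa3, stood at −1.34, −0.62 and −0.16 (SE 0.45, 0.15 and 0.12), and Cygb, Slit3 and Cxcl12 were called lower, all named after their values were seen. Each of these calls was lost on leaving out any of at least 3 mice, and those of Slit3 and Cxcl12 also without the block. Whether fibroblast RNA came from attached or engulfed cells, free RNA or sorting impurity was not tested, and neither was a difference in the macrophages that covers matrix and other fibroblast genes alike.

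Genes that are not protein-coding were called almost only in the higher direction. Length or GC trends are argued against for the 56 such genes with a biotype, whose median was 1.306 after the correction in the blocked fit and 1.323 before. These genes were picked by their calls, and the shift of the wider set of 765 genes given below was not computed after the correction. Greater depth of the mtD2+ libraries is argued against by their totals, larger than those of mtD2− in 2 of 4 mice (mean log2 ratio −0.09, SD 0.223). Thinning to the smallest library, after which 54 stayed called, decides nothing for that reason. More genes were detected in mtD2+ in 4 of 4 mice all the same (18506 ± 528, against 17721 ± 484 in mtD2−, exact paired p = 0.125). What part that difference has in these calls was not tested. Reads of an overlapping protein-coding gene called higher are argued against as the whole cause by the 17.9% of the non-coding genes (10 of 56) that overlap one. Of the 56, 29 overlap some tested protein-coding gene. Since 459 of all 12220 tested protein-coding genes were called higher, shared reads stay open for those 10. Shared reads stay open too for the rest of the 29, whose partner genes may have risen without a call. A larger share of nuclear or unspliced RNA in the mtD2+ libraries stays open and is consistent with a shift of 0.38 (bootstrap 0.326 to 0.447) of all 765 tested lincRNA, antisense and sense-intronic genes above protein-coding genes of like expression. Whether that share reflects the cells or their handling was not tested.

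The summed mitochondrial-genome mRNAs were higher in mtD2+ in all 4 mice, while 0 of the 8 tested passed over all genes. A single mouse is argued against by the smallest of the 4 log2 ratios, 0.252, and by a median of 0.405 without mouse 4, and a rise of both genomes' respiratory chain genes by the nuclear-encoded median of −0.301. A loss of cytosolic mRNA could leave nuclear and mitochondrial RNA enriched. The mouse with the largest mitochondrial ratio also had the largest Malat1 ratio (1.442), as written in advance, but Neat1 rose most in mouse 3 (2.278, against 1.07 in mouse 4). Ribosomal RNA of the mitochondria lagged behind the mRNAs in all 4 mice (mean gap 0.61, SD 0.389, exact sign-flip p = 0.125, the smallest that 4 pairs allow). That gap set TMM-scaled mRNA ratios against ribosomal RNA ratios scaled by library totals. As shares of library totals, the mean log2 ratios were 0.742 for the mRNAs and 0.188 for the ribosomal RNA. RNA brought by adipocyte mitochondria, or by more mitochondria of any source, would raise both kinds of mitochondrial RNA, and mt-Rnr1 stood at 0.11 (SE 0.16) and mt-Rnr2 at 0.253 (SE 0.14). To exclude this, both had to lie, by more than their errors, under 0.5 of the median of the mRNAs, and mt-Rnr1 did while mt-Rnr2 did not. These explanations cannot be told apart here, since reads from adipocyte and macrophage mitochondria were not separable by gene counts.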

How the results depend on the processing

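All tests in this part were planned. All genes called in the chosen analysis and tested under an alternative kept their direction there. Without the replicate block, 218 genes passed (147 higher, 71 lower), 217 of them called with it. The DESeq2 Wald test called 1790 (1117 higher, 673 lower), including all 767, and a test against a fold of 1.2 called 337 (255 higher, 82 lower). Leaving out each mouse in turn gave 166 to 555 calls (120 to 432 higher, 46 to 123 lower), with fewer samples. The other 10 settings gave 729 to 1066 calls. Of the 11 lists past camera, 0 passed with an estimated correlation and 0 with fry, and without the block 2 were lost, the interferon (0.0508) and stress (0.0911) lists. Leaving out a mouse ended only the call of the stress list (0.0796, 0.133 and 0.0621 without mouse 1, 2 and 3). The log2 fold change of Ptprc, never called, turned to −0.038 with library totals, −0.277 with the length and GC correction and −0.063 without mouse 4 (leaving out each mouse, −0.063 to 0.063), and that of mt-Rnr1, never called, came to 0 without mouse 4 (0 to 0.328), and the cause was not tested. Of 100 called genes named in the text, 19 kept the call in every setting that tested them, 67 lost it without the block, 40 against a fold of 1.2, and 61, 53, 68 and 24 without mouse 1, 2, 3 and 4. Of 15 named genes not called, 11 passed in some setting. Thinning to the smallest library gave 810 calls, 746 of them shared, and what greater depth would add was not tested.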

Other observations

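The clock and TFEB lists and the count of AUUUA elements were chosen only after the gene results of the study were seen, though before the values of the list members or the correlation. An exception is 2 TFEB list members that the fixed lists also hold. Flcn, Rragc and Fnip1, genes of the lysosomal nutrient-sensing machinery, rose by log2 0.71, 0.73 and 0.89 in mtD2+ (SE 0.10, 0.10 and 0.13, edgeR adjusted p = 0.00735, 0.00741 and 0.00778). Fnip2, a partner of Flcn, rose 1.10 (SE 0.12, adjusted p = 0.00323). The clock genes Nr1d1, Dbp and Per1 rose 1.453, 0.78 and 0.49 (SE 0.23, 0.15 and 0.10, adjusted p = 0.00995, 0.019 and 0.0273). These genes were named after their values were seen. Fnip2 kept its call whichever mouse was left out. Fnip1 lost its call without 1 mouse, Flcn, Rragc and Nr1d1 without either of 2, and Dbp and Per1 without any of 3, and all of these except Fnip1 also lost it without the block.

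The higher Trpm1, Fnip2, Neu1 and Gla led to the hypothesis that the transcription factors TFEB, TFE3 or MITF may be more active in mtD2+ cells. A list of 15 other targets had a median log2 fold change of 0.341 (bootstrap 0.105 to 0.71), 5 rose and 0 fell over all genes, and the summed list was higher by 0.38, 0.42, 0.43 and 0.39 in the 4 mice. That is consistent with the hypothesis, but the fixed list of 45 lysosome genes, a main class of targets that includes Neu1 and Gla, had a median of 0.003 (bootstrap −0.086 to 0.146), and 6 of its genes rose and 3 fell over all genes. The hypothesis stays open, and protein activity was not tested. The fixed lists hold 2 of the 15 genes, and Flcn, a partner of Fnip2, is also among the 15. The list is thus not wholly independent of the results that led to the hypothesis.

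The higher Ciart and Bhlhe41 led to the hypothesis that the clock of mtD2+ cells may stand at another phase. Genes of the clock's output and of its activator phase would then move apart, and their medians differed by −0.085 (bootstrap −0.552 to 0.602), which is too wide to decide. Both were positive, at 0.44 over 10 genes and 0.53 over 4.

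Short-lived mRNAs, which often carry AUUUA elements in the 3′ UTR, may be enriched among the higher genes. Across 12156 protein-coding genes with a 3′ UTR, the partial Spearman correlation of log2 fold change with the number of AUUUA elements, given UTR length, UTR GC content and expression, was 0.047 (permutation p = 1e-05, the smallest that 100000 permutations can give). The median was −0.11 for 3732 genes with no element and 0.03 for 4601 genes with at least 3. The relation is weak, it runs across genes, and genes are not independent replicates.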
